A study of Homo sapiens and Mus musculus with 20 samples.

How the data were processed

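Single cells of embryonic mouse back tissue (E13.5, E14.5, E15.5) and of human NCRM1 cultures (days 6, 10, 15, 20 and 30 of differentiation, days 20 and 40 after replating) were profiled with inDrops. The submitters' processing notes name Trimmomatic for read trimming, Bowtie 1.2.2 for alignment, and the builds GRCh38 and GRCm38. How molecules were counted and cells were filtered is not stated there. Reads were not aligned again.

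The matrices deposited by the authors held, for each gene and cell, the natural log of 1 plus the count of UMIs, not scaled per cell. This was read from the values: inverting the log gave whole numbers, at most 4.7e-07 away in relative terms. The recovered totals equalled the UMI count per cell that the authors deposited for all 20000 mouse cells, 8987 of 14313 cells of days 6 to 30 and 2854 of 6676 replated cells, with a median ratio of 0.9998 in the last. The deposited fraction of UMIs from mitochondrially encoded genes was taken from the authors' cell tables. The doublet score per cell was also as deposited by the authors, who had marked 0 of the cells as doublets. Class names came from the authors' cell tables. Names of libraries were mapped to samples with 0 left over; libraries named day 40 and 60 in the replated table were read as days 20 and 40 after replating. Libraries with the suffix a or b were summed as 1 replicate, as their labels do not say what the suffix means.

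The mouse table held cells with 904 to 27728 UMIs, the table of days 6 to 30 cells with 802 to 34802, and the replated table cells with 1003 to 36869. All deposited cells were kept. Scrublet, run in scanpy 1.11.5, marked 25, 21 and 29 cells as doublets (0.125%, 0.147% and 0.434%), which stayed in and were left out in an alternative. Libraries held from 3331298 UMIs (day 30, 2a) to 15616155 (E15.5, 2b). A floor of 3 counts was used for the folds of genes not seen, and shares of 0 cells are given with their exact upper limit. Bounds of the form "at least" divide the level by that floor over the whole group.

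Counts were summed per replicate and class (pseudobulk), so that replicates and not cells were the unit, with at least 20 cells per replicate and class. edgeR 4.0.16 in R 4.3.3 filtered low counts, normalized by TMM and ran quasi-likelihood F tests (two-sided) with Benjamini-Hochberg adjustment over the genes tested; 0.05 was the threshold. Mouse stages were compared within precursors and within adipocytes, 2 replicates per stage. Adipocytes and precursors of the same replicates were compared with the sample as a block (6 replicates in mouse, 4 in human, where fibroblasts were a further partner). Replated days were compared over the whole culture and within adipocytes. Day 30 was compared with each replated day over the whole culture. Levels beside tests are means and SDs of TMM-normalized CPM; other levels are plain CPM. Sex-linked genes were left out of the human tables.

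The 14 gene lists were fixed before the data were examined: thermogenic genes, adipogenic regulators, lipid storage, fatty acid oxidation, TCA cycle, nuclear respiratory chain, glycolysis, cholesterol synthesis, brown-fat precursor genes, cell cycle, extracellular matrix, BMP and TGF-beta, Wnt, and the response to dissociation. Camera in limma 3.58.1 tested each list with a preset correlation of 0.01, adjusted over the lists of a comparison, and again with a correlation estimated from the data. Genes were named by a rule also fixed before the data were examined: passing, the same direction between every pair of replicates or in every block, a mean of at least 20 CPM in the higher group, an official symbol of a named gene, and the 8 largest changes each way, of which the text takes a part. Up to 4 members per list were taken by smallest p, and GATA6 and UCP1 were always given. For human days the 5 genes with the largest fold over the mean of the other days were taken, at 50 CPM or more. Marker sets of cell types served to describe classes.

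Mouse class shares were tested with an exact permutation of stage labels (two-sided slope), adjusted over 18 classes. Shares carry exact Clopper-Pearson and levels exact Poisson 95% intervals. Human and mouse classes with at least 50 cells were compared by Spearman correlation of log levels, with 10 CPM added, over the 3000 most variable shared genes, centred over classes. Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, anndata 0.12.19 and matplotlib 3.10.9 were used.

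Each comparison was tested on a single draw of simulated data with 200 genes changed, all taken from genes above the median level. The spread between replicates was taken from its trend over genes. The rates below do not cover genes of lower level. Changes of 2-fold and 4-fold were found in 96% and 100% of cases in precursors from E13.5 to E14.5 (11201 genes), 95% and 100% from E14.5 to E15.5 (11189) and 96% and 100% over both days (11188). In mouse adipocytes these were 22% and 84% (7015 genes), 88% and 100% (6948) and 19% and 86% (6980). For adipocytes against precursors they were 43% and 100% in mouse (9727) and 91% and 100% in human (8296), and 97% and 100% against fibroblasts (11378). The whole replated culture gave 100% for both (15537), replated adipocytes 78% and 100% (9405), and the comparisons with day 30 gave 93% and 100% (16175) and 98% and 100% (16156). Between 3 and 12 false calls were made. In 200 simulations of shares, a 1.5-fold rise per day in 1 class was found in 100% of cases at an unadjusted p under 0.05 but in 0.5% after adjustment over 18 classes; a slope was found in 3% without one, unadjusted.

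Alternatives chosen before the data were examined were DESeq2 1.42.0, its size factors, no filter on low counts, each replicate left out, blocks, separate a and b libraries, cells with 1000 UMIs or more and marked doublets left out. For shares there were also other denominators and edgeR, and for correspondence other gene numbers and Pearson correlation. Days 6 to 20 had 1 library each and were described without tests, with cells thinned to 1000 UMIs as an alternative. Some genes were tested but are not reported here, and the counts of single-gene alternatives leave them out.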

Results

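Gene expression was measured in single cells of embryonic mouse back tissue and of human cultures differentiated toward brown fat, a tissue that burns fuel to make heat. The assay was inDrops, a droplet method that marks each captured transcript with a unique molecular identifier (UMI), so that UMIs count molecules. The mouse tissue came from wild-type CD1 IGS embryos, an outbred stock, at embryonic day (E) 13.5, 14.5 and 15.5, with 2 replicates per stage. It lay over the ribs at the height of the forelimbs, where interscapular brown fat forms. At E15.5 the skin had been taken off before the cells were released, so the loss of skin classes and the stage cannot be told apart. The human cells were NCRM1, an induced pluripotent stem cell line that carried the red fluorescent protein mCherry as a reporter of UCP1, the uncoupling protein of brown fat mitochondria. Days 6, 10, 15 and 20 of differentiation had 1 library each; day 30 and days 20 and 40 after replating had 2 replicates each. The labels say that the samples with 2 replicates came from 2 independent human differentiations. They do not say whether mouse replicates were separate embryos, nor whether a human replicate number marked the same differentiation on each day.

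The mouse table held 20000 cells with 94643354 UMIs, the table of human days 6 to 30 held 14313 cells with 67377241 UMIs, and the replated table held 6676 cells with 33493303 UMIs. Replicates 1 and 2 had 8016103 and 7720887 UMIs at E13.5, 11598197 and 11622663 at E14.5, and 28987555 and 26697949 at E15.5. Human days 6, 10, 15 and 20 had 10804249, 11475905, 8244627 and 5764974 UMIs, and the day 30 replicates had 14980502 and 16106984. After replating the totals were 7877658 and 6228399 on day 20, and 10619307 and 8767939 on day 40. The labels state 2500 cells collected for each of days 6 to 20, and the table held 1908, 3177, 2509 and 1911. At least 3000 cells per sample are stated for the later days, against 1934 and 2874 held on day 30, 1348 and 805 on day 20 after replating, and 2359 and 2164 on day 40. Levels are given as CPM, the UMIs of a gene scaled to the total of the cells summed. Intervals are exact 95% intervals (Clopper-Pearson for shares, Poisson for levels) and cover counting error only.

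Each cell carried a class name from the authors, and those names are used as they stand. The class BA was led by fat-cell genes in both species, among them the lipid droplet gene Cidec in mouse and the fat-cell hormone gene ADIPOQ in human, and its cells are called adipocytes. Of its 5377 mouse cells 5118 came from E15.5, so the leading genes mostly describe that stage. At E13.5 and E14.5 it held 0 UMIs of Cidea, another leading gene. The fat-cell regulator Pparg then stood at 170 and 294 CPM, against 68.4 and 93.8 in BApre. BApre cells are called precursors. In the mouse they stood out most for a set of brown-fat precursor markers, by a mean of 1.69 on the log2 scale over the other classes. The same set was also the best for the mouse classes Conn tissue (1.34) and Dpre (0.994), so it did not single out BApre. In the human day 6 to 30 table the best set for BApre was tendon, at 1.43, ahead of brown-fat precursor markers at 0.64. After replating, the class named SMC was led by skeletal muscle genes (4.26) rather than smooth muscle genes (1.33), and the mouse class RBC mixed globin genes with bone and nerve genes.

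The first comparison asked how the make-up of the mouse back changed over the 2 days in which brown fat forms. Adipocytes went from 1.07% ± 0.254 of cells (mean ± SD, n = 2) at E13.5 to 3.56% ± 1.45 at E14.5 and 53.5% ± 10.8 at E15.5. Precursors stayed at 16.0% ± 0.189, 15.8% ± 1.27 and 16.1% ± 2.52. The tendon-like class Cpre went from 18.4% ± 1.07 over 13.8% ± 0.935 to 1.25% ± 0.642, and macrophages from 7.55% ± 0.398 over 3.67% to 2.80%. Endothelial cells (EC) held 16.0% ± 0.121 at E13.5 and 4.32% at E14.5. The muscle precursor class SkMpre was highest at E14.5, at 8.70%. Dermis (12.1% ± 0.706 at E13.5), the class Dpre and epidermis were close to 0 at E15.5, where skin had been removed. An exact two-sided permutation test of the slope over 6 replicates gave p = 0.0222, the smallest of 90 arrangements, for 6 classes: adipocytes at 26.2 percentage points per day, Cpre at -8.60, Dermis at -6.02, Dpre at -2.25, Macrophage at -2.37 and Meninges at -1.03. Adjusted over 18 classes that p was 0.0667, so 0 classes passed; in simulations the adjusted test found a 1.5-fold rise per day of 1 class in 0.5% of cases. By contrast, edgeR's quasi-likelihood test on cell numbers passed 2, adipocytes and meninges. Shares are of all cells, so a class can lose share because another gained. The highest mitochondrial share of a deposited cell was 24.73% and 24.59% in the E13.5 libraries, but 19.87% and 19.33% at E14.5. In the E15.5 libraries it was 24.92% to 24.97%. Adipocytes had the highest median of the mouse classes, 17.5% over all stages. A lower limit at E14.5 would thus leave out adipocytes more than other classes. In E15.5 libraries 1a, 1b, 2a and 2b, 340, 254, 487 and 464 cells of any class held 20% or more, against 5118 adipocytes at that stage. E13.5, with an upper range like that of E15.5, held 1.07% adipocytes. The lower limit at E14.5 thus cannot account for most of the adipocyte rise to E15.5. The exact part it played stays open.

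**Figure D1:**
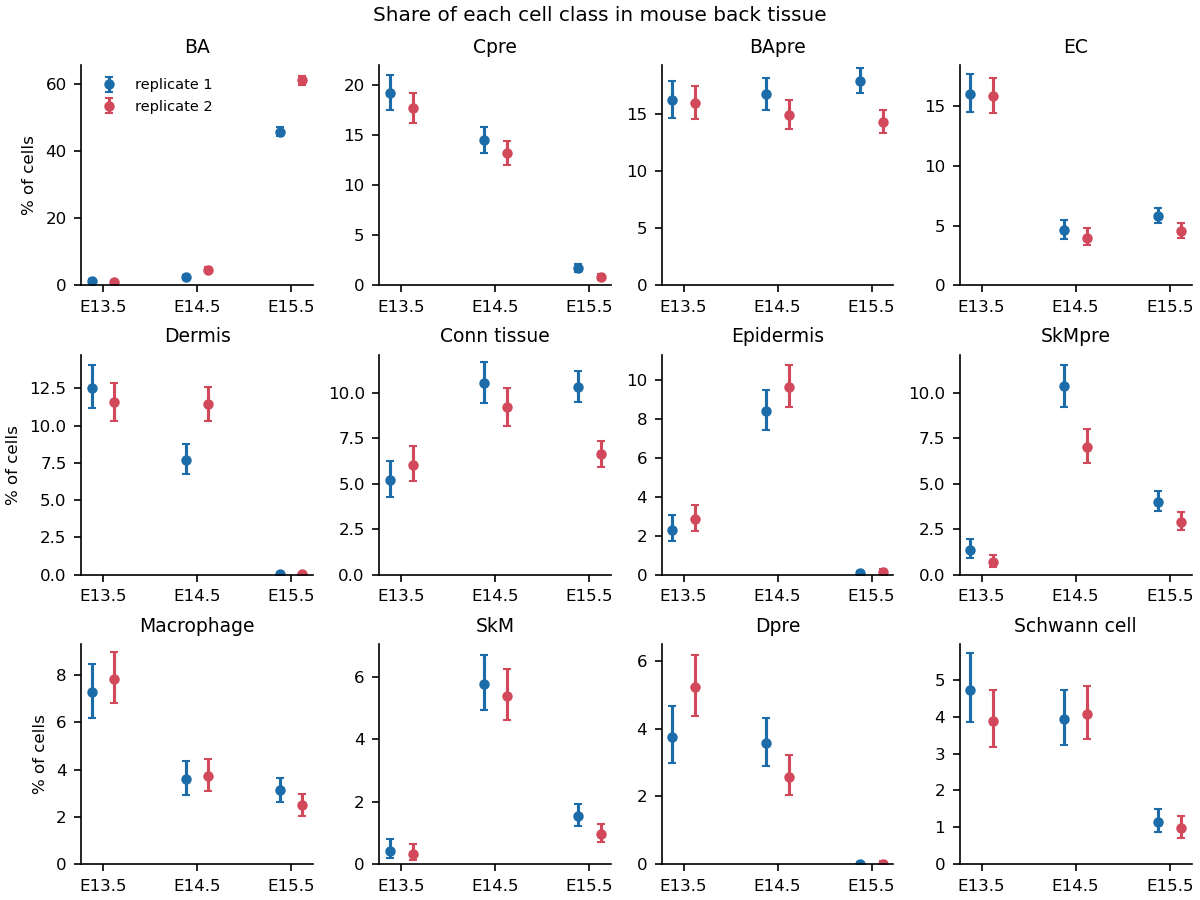
Share of all cells (%, vertical axis) at E13.5, E14.5 and E15.5 for the 12 classes with the highest stage mean, each point 1 replicate with its exact 95% binomial interval. Adipocytes (BA) reach 53.5% on average at E15.5, while precursors (BApre) stay near 16.0%.

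How precursors themselves changed was asked first for E14.5 against E13.5. The carbonic anhydrase gene Car3, abundant in fat and muscle, rose from 20.9 to 127.7 ± 4.29 CPM (mean ± SD, n = 2; log2 change 2.61 ± 0.20 SE, adjusted p = 1.61e-07, edgeR). The lipid carrier Fabp4 rose by 1.97 and the fatty acid transporter Cd36 by 1.91 on the log2 scale. No level of free RNA, that is RNA from other cells, was estimated for this day. In both contrasts with E15.5, Car3 lay at or below that level in precursors. Over this day the muscle class SkM went from 0.379% to 5.58% of cells and adipocytes from 1.07% to 3.56%. Carry-over from such cells was thus not excluded for these 3 genes. The basement membrane collagen Col15a1 rose by 1.69. Ppargc1b, a coactivator of mitochondrial genes, fell by 2.18 and the retinol receptor Stra6 fell by 1.87. In all, 84 genes rose and 131 fell of 11512 tested. That total of 215 was 122 with DESeq2, 70 and 78 without E13.5 replicates 1 and 2, 95 and 142 without E14.5 replicates 1 and 2, and 342 and 341 without E15.5 replicates 1 and 2, which share the fit; 14 of the 215 went beyond the change in other classes. More genes fell than rose in these totals except among those 14 (10 up, 4 down); with no low count filter, 210 rose and 172 fell. Of the 205 called genes that were tested in endothelial, macrophage, Schwann and mast cells together, 190 moved the same way there and 120 by at least 50% of the log2 change. Among 34 nuclear genes of the respiratory chain, the electron transport machinery of mitochondria, 5 rose and 0 fell, with 11 and 0 adjusted over the list alone; members that rose included the complex IV genes Cox6b1 and Cox4i1. Camera gave an adjusted p = 8.81e-05 for that list, and 0.746 with an estimated correlation. Of 24 genes for lipid storage in adipocytes, 3 rose and 1 fell, with 4 and 2 adjusted over the list alone (camera adjusted p = 0.00452, and 0.453 with an estimated correlation).

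Between E14.5 and E15.5 precursors gained matrix genes and lost genes for making cholesterol. Of 31 extracellular matrix genes, 28 rose and 0 fell, with the same numbers adjusted over the list alone. Microfibril gene Mfap5 rose by 2.10, the fibrillin Fbn1 by 1.49 and the collagen Col6a1 by 1.55 on the log2 scale; camera gave adjusted p = 2.54e-16, and 0.385 with an estimated correlation. Of 18 genes for cholesterol synthesis, 0 rose and 17 fell, also 17 adjusted over the list alone, among them the demethylase Cyp51 at -1.30 and the early synthase Hmgcs1 at -0.95 (camera adjusted p = 1.22e-09, and 0.385 with an estimated correlation). The BMP and TGF-beta list had 2 members up and 10 down of 23, with 4 and 10 adjusted over the list alone. Its BMP targets Id1 and Id3 fell by 1.60 and 1.40, while the ligand Bmp4 rose by 1.69 (camera adjusted p = 0.0221, and 0.385 with an estimated correlation). Largest among single genes were Ly6f and Ly6a, surface proteins of the Ly6 family, at 5.30 and 3.80, the angiotensin precursor Agt at 4.06 and the mitochondrial gene Ndufa4l2 at 4.39. Ly6f went from 2.10 ± 2.32 to 78.9 ± 27.3 CPM (n = 2). The chromatin gene Hmga2, active in embryonic growth, fell by 3.71 (67.8 ± 1.77 to 4.86 ± 2.48 CPM, adjusted p = 4.17e-09). In all, 1377 genes rose and 1134 fell. The total of 2511 was 1278 with DESeq2 and 1218 without E14.5 replicate 1. Of 2229 called genes tested in the other 4 classes, 998 moved there the same way by at least 50% of the log2 change, and 586 calls went beyond it.

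Over both days, from E13.5 to E15.5, 1317 genes rose and 1133 fell in precursors. The total of 2450 was 1364 with DESeq2, and 1345 and 1453 without E13.5 replicates 1 and 2. In the other 4 classes 791 of 2157 moved the same way by at least 50% of the log2 change, and 724 calls went beyond it. Fabp4 rose from 9.95 ± 3.58 to 369 ± 33.0 CPM (log2 change 5.21, adjusted p = 2.44e-13). At E15.5 precursors held 5.58% of the level of Fabp4 in the whole library. Adipocyte markers stood at a median of 5.22% in 9 other classes (from 1.15% in SkM to 69.7% in RBC), which was taken as the level of free RNA although the classes were not tested for expression of their own. At or below that median were 7 rising calls, among them Car3 and the lipid storage genes Pnpla2 and Adipoq. Ly6a rose by 5.79, and the fat-cell lipase Lpl by 2.58. Ndufa4l2 had 3 UMIs at E13.5, and its ratio was 69.8 (95% counting interval 23.8 to 340). Hmga2 fell by 3.87, the cartilage gene Cnmd by 3.80 and Stra6 by 3.60. Gata6, a transcription factor of the precursor marker list, fell by 0.61 ± 0.14 (SE) from 182 ± 3.77 to 119 ± 17.9 CPM (adjusted p = 0.00274); its changes over each single day, -0.30 and -0.32, did not pass. Matrix genes rose in 27 of 31 cases and 1 fell, with 29 and 1 adjusted over the list alone (camera adjusted p = 5.65e-15, and 0.307 with an estimated correlation). Lipid storage genes showed 12 up and 4 down of 24, with 15 and 4 adjusted over the list alone (camera adjusted p = 0.000598, and 0.307 with an estimated correlation), a count that includes the members at the level of free RNA. Of 16 genes of the Wnt pathway 2 rose and 9 fell, with the same numbers adjusted over the list alone, among them the Wnt inhibitors Sfrp2 (-1.48) and Dkk2 (-1.15); camera gave adjusted p = 0.0676, and 0.307 with an estimated correlation. Embryo sex went along with stage: the Y-linked gene Ddx3y was at 85.7 and 101 CPM at E13.5, 113 and 2.50 at E14.5, and 0.451 to 1.36 in the E15.5 libraries.

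The same contrasts were asked of adipocytes, which were few before E15.5 (48 cells at E13.5, 211 at E14.5 and 5118 at E15.5). The E14.5 cells reached lower mitochondrial shares than those of the other stages, so contrasts with E14.5 cover unlike ranges. From E13.5 to E14.5, 0 genes rose and 3 fell of 7774 tested by edgeR, with 807 at an unadjusted p under 0.05, and DESeq2 called 55 (7 up, 48 down). edgeR called 0 without E13.5 replicate 1 or 2 or E14.5 replicate 2, 100 without E14.5 replicate 1 (80 up, 20 down), 25 and 23 without E15.5 replicates 1 and 2 (15 and 13 up, 10 and 10 down), and 55 with no low count filter (39 up, 16 down), so the balance of directions depended on the setting. The actin-binding gene Tmsb4x fell from 593 ± 106 to 153.5 ± 64.2 CPM (log2 change -2.01, adjusted p = 0.00585). Plagl1, an imprinted transcription factor, fell by 2.12 (adjusted p = 0.0286). The third, the unnamed locus Gm8797, lies outside the naming rule and was looked up after its values were seen. Camera put nuclear respiratory chain genes up (adjusted p = 0.00323, and 0.818 with an estimated correlation), with 0 of 34 members passing and 4 adjusted over the list alone.

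Between E14.5 and E15.5 respiratory chain and fatty acid oxidation genes rose in the adipocyte class, over cells of unlike mitochondrial ranges. With only cells under 20% mitochondrial UMIs, 734 of 737 passing values over all mouse and human comparisons kept their side of the threshold. Cidea, a lipid droplet protein of brown fat, had 0 UMIs at E14.5 and 311 ± 22.7 CPM at E15.5 (n = 2), at least 118-fold higher against a floor of 3 counts over the group. Cox8b, a complex IV subunit of fat and muscle, was at least 32.6-fold higher. All 34 nuclear respiratory chain genes rose, as did all 18 of the tricarboxylic acid (TCA) cycle and all 18 of fatty acid oxidation, with the same numbers adjusted over each list alone. The oxidation enzyme Acadm rose by 3.12 and the complex IV gene Cox5a by 2.66 on the log2 scale. Camera gave adjusted p = 2.83e-19, 2.64e-11 and 2.98e-11 for these lists, and 0.142 for each with an estimated correlation. Of 17 thermogenic genes of brown fat 13 rose and 2 fell, also adjusted over the list alone (camera adjusted p = 4.12e-06, and 0.142 with an estimated correlation). Of 28 lipid storage genes 21 rose and 4 fell, with 23 and 4 adjusted over the list alone; the triglyceride lipase Pnpla2 rose by 4.97 (camera adjusted p = 1.02e-07, and 0.142 with an estimated correlation). Glycolysis genes rose in 8 of 14 cases and 1 fell, with the same numbers adjusted over the list alone (camera adjusted p = 0.0461, and 0.151 with an estimated correlation). With a replicate block the camera adjusted p of glycolysis was 0.0625, so that list no longer passed. Matrix genes went down in 19 of 28 cases and up in 2, also adjusted over the list alone, with the collagens Col3a1 and Col1a1 falling by 2.71 and 2.70 (camera adjusted p = 5e-09, and 0.142 with an estimated correlation).

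Part of the precursor genes fell in adipocytes over the same day. Gata6 went from 113 ± 24.0 to 28.3 ± 2.42 CPM (log2 change -1.96 ± 0.22 SE, adjusted p = 5.42e-07). The growth regulator Dlk1, a preadipocyte marker, fell by 2.19, the receptor Pdgfra by 2.86 and the heparan sulfate protein Gpc3 by 2.57. Of 13 precursor genes of brown fat 2 rose and 7 fell, with 3 and 7 adjusted over the list alone (camera adjusted p = 0.00241, and 0.142 with an estimated correlation). Among single genes the retinoic acid binding gene Crabp1 fell by 5.26 and the Wnt inhibitor Sfrp2 by 5.68. In all, 1872 genes rose and 1601 fell, 3473 together; without E15.5 replicates 1 and 2 the totals were 2288 and 2122, and 2114 calls went beyond the change in other classes. Ddx3y also fell, by 5.52, and its replicates at E14.5 differed (51.7 ± 67.5 CPM). Ucp1 itself had 0, 1 and 292 UMIs in adipocytes at the 3 stages, 8.67 CPM (7.70 to 9.72) at E15.5, below the filter for testing.

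From E13.5 to E15.5, 1071 genes rose and 689 fell in adipocytes, while DESeq2 gave 919 up and 952 down. The total of 1760 was 911 and 917 without E13.5 replicates 1 and 2. Chchd10, a mitochondrial protein of heat-making fat, was at least 67.3-fold higher, the coenzyme Q kinase Coq8a at least 40.3-fold and Cox7a1, a heart and brown fat form of complex IV, at least 12.5-fold. All 34 nuclear respiratory chain genes rose, adjusted over the list alone too (camera adjusted p = 2.43e-14, and 0.198 with an estimated correlation). Thermogenic genes showed 11 up and 1 down of 17, with 13 and 1 adjusted over the list alone (camera adjusted p = 1.47e-06, and 0.177 with an estimated correlation). Follistatin (Fst), a blocker of activin and myostatin, fell by 5.92. Gata6 fell by 1.54 ± 0.49 (SE, adjusted p = 0.0279). The median log2 change over all genes tested was 0.11, which single changes include.

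Adipocytes and precursors of the same replicate were compared over all 6 mouse replicates. The classes were drawn from expression, so genes that define them are not independent findings. Adipocytes were higher in 2244 genes and lower in 2691 of 10227; without E15.5 replicates 1 and 2 the total of 4935 was 3208 and 3264. Car3 (5.29), the hormone gene Adipoq (5.12), the hormone-sensitive lipase gene Lipe (5.03) and Fabp4 (4.65) had the highest log2 differences among named genes, with Car3 at 10894 ± 13744 CPM against 166 ± 152 (SD, n = 6). Mfap5 was lower by 9.58, the growth-factor binding gene Igfbp6 by 9.36 and Ly6a by 9.17. The signal Sfrp4 was lower 467-fold (counting interval 159 to 2270), on 3 UMIs in adipocytes. Gata6 was lower by 1.25 ± 0.28 (SE; 73.6 ± 40.1 against 151 ± 29.9 CPM, adjusted p = 0.00584). Cell cycle genes were higher in adipocytes in 13 of 24 cases and lower in 0, with 15 and 0 adjusted over the list alone, among them the survivin gene Birc5 and the mitotic kinase Plk1 (camera adjusted p = 6.02e-07, and 0.249 with an estimated correlation). Fatty acid oxidation genes were higher in 10 of 19 cases and lower in 1, with 12 and 1 adjusted over the list alone (camera adjusted p = 7.94e-05, and 0.378 with an estimated correlation). Matrix genes were lower in 28 of 31 cases and higher in 0, with 29 lower adjusted over the list alone (camera adjusted p = 5.97e-11, and 0.312 with an estimated correlation). BMP and TGF-beta genes were lower in 16 of 19 cases, also adjusted over the list alone; the log2 differences of Bmp7 and Bmp4 were -7.32 and -6.55 (camera adjusted p = 1.93e-05, and 0.123 with an estimated correlation).

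**Figure D2:**
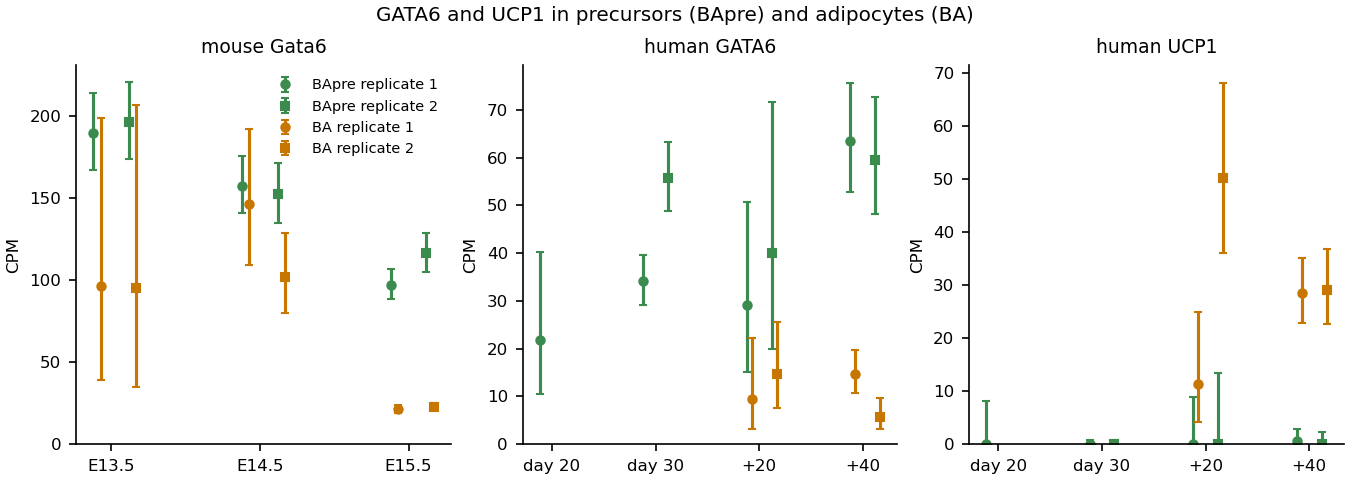
Levels (CPM, vertical axes from 0) of Gata6 in mouse stages and of GATA6 and UCP1 on human days 20 and 30 and days 20 and 40 after replating (+20, +40), in precursors (green) and adipocytes (orange), 1 point per replicate with its exact 95% Poisson interval. UCP1 stands above 0 in adipocytes, while precursors held 1 UMI in all.

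The human cultures were followed from presomitic mesoderm onward. On day 6, 96.8% of 1908 cells belonged to the class PSM, and the presomitic factor TBX6 stood at 62.0 CPM. On day 10, 49.0% (47.3 to 50.8) were in class PAX3- and 38.6% (36.9 to 40.3) in PAX3+; the somite factor MEOX1 rose from 19.4 to 163 CPM and PAX3, a factor of the dermomyotome, from 1.67 to 50.7. Day 15 held 32.7% (30.9 to 34.6) cells of the cartilage-like class Cpre and 21.4% of the neural class Neuro1. Precursors were 0 of 1908 cells on day 6 (upper limit 0.193%), 0 of 3177 on day 10 (upper limit 0.116%), 0.359% on day 15, 6.75% (5.67 to 7.97) on day 20 and 24.8% ± 3.61 (SD, n = 2) on day 30. Also on day 30, SkMpre held 21.8% ± 0.377, SkM 12.8% ± 2.95, Fibroblast 13.9% ± 0.141 and SMC 9.97% ± 3.86. Days 6 to 20 had no replicate, so no test was run across days.

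**Figure D3:**
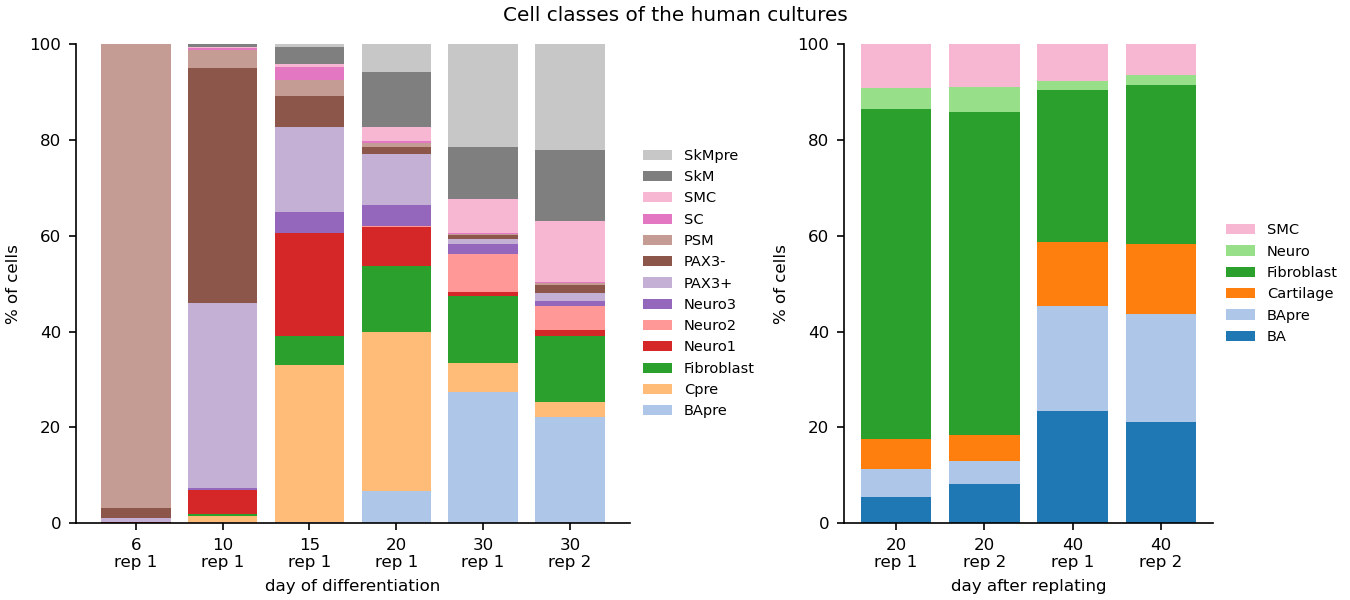
Stacked shares of cell classes (% of cells) per replicate on days 6 to 30 of differentiation (left) and on days 20 and 40 after replating (right), whose classes were named separately. PSM fills 96.8% of day 6, and adipocytes (BA) go from 6.87% to 22.3% after replating.

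For each day the 5 genes with the largest fold over the mean of the other days were taken, in part named here. Those of day 6 included SP5, a Wnt target, at 311 CPM (122-fold) and GAD1, an enzyme of GABA synthesis, at 106 CPM (135-fold). Those of day 10, up to 12.5-fold, included BMP2, a bone morphogenetic protein, at 58.9 CPM (10.9-fold) and MEOX1 (9.27-fold). On day 15 OLIG3 and POU3F2, neural transcription factors, were 17.9-fold and 5.07-fold higher. Cartilage genes were among those of day 20, with MATN4 at 94.9 CPM (13.1-fold) and the collagens COL9A3 and COL9A2 at 6.85-fold and 6.45-fold. Those of day 30, up to 29.5-fold, included SFRP4, a Wnt modulator, at 350.3 CPM (26.4-fold) and ASPN, a matrix protein, at 310.3 CPM (16.2-fold). Sums of some marker sets moved with the classes. Presomitic markers fell from 930 CPM on day 6 to 99.9 on day 10. Skeletal muscle markers went from 252 on day 6 to 3811 on day 20 and 5131 and 7254 in the day 30 replicates. Cartilage markers were highest on day 20, at 1549 CPM. The sum of nerve markers did not move with the neural classes. It was highest on day 10, at 2191 CPM, when Neuro1 held 5.10% and Neuro3 0.378% of cells. Abundant members weigh most in such a sum. TUBB3 made up only 17.4 CPM of it on day 10 and 19.5 on day 15. As a mean over members, the nerve set did mark Neuro3, by 5.06 on the log2 scale. On day 15 Neuro1 and Neuro3 held 21.4% and 4.50% of cells. GATA6 was at 1.30, 0.436 and 0.728 CPM on days 6, 10 and 15, at 5.38 on day 20 and at 26.8 and 43.2 on day 30. With each cell thinned to 1000 UMIs it was at 3.71, 0.656 and 0.405 CPM on days 6, 10 and 15. After thinning it stood at 7.03 on day 20 and at 23.3 and 39.3 on day 30. Within day 30 it was at 44.0 CPM in precursors, 101 in SMC and 132 in PAX3-. PPARG, the master regulator of fat cells, stayed between 0.610 and 1.09 CPM throughout. UCP1 had 0 UMIs in 1166 precursor cells of day 30 (upper limit 0.401 CPM).

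After replating the cultures were asked how they had changed between days 20 and 40. Adipocytes went from 6.87% ± 2.06 (SD, n = 2) to 22.3% ± 1.58 of cells and precursors from 5.29% ± 0.806 to 22.2% ± 0.476. Cartilage cells went from 5.79% ± 0.629 to 14.0% ± 0.788, while fibroblasts went from 68.1% ± 1.12 to 32.4% ± 1.10. These shares were described without a test; their differences exceeded the spread between replicates. UCP1 lay almost wholly in adipocytes, at 35.0 CPM (25.7 to 46.5; 47 UMIs in 140 cells; 11.4 and 50.1 CPM in replicates 1 and 2) on day 20 and 28.7 CPM (24.5 to 33.6; 160 UMIs in 1012 cells) on day 40. Every other class held 0 to 2 UMIs per day.

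In the whole culture 4557 genes rose and 4593 fell between these days, of 16220 (9150 together, and 5796 with DESeq2). These changes include the shift in class shares, with adipocytes going from 6.87% to 22.3% of cells and precursors from 5.29% to 22.2%. Single genes that rose included the cartilage link protein HAPLN1, from 0.622 ± 0.157 to 1359 ± 86.3 CPM (log2 change 11.02, adjusted p = 3.66e-17), the collagen COL2A1 (8.66) and the proteoglycan ACAN (7.04). Among those that fell were the early response factor FOSB, by 7.69 (414 ± 94.0 to 2.02 ± 0.401 CPM), the prostaglandin synthase PTGS2 by 6.19 and the orphan receptor NR4A1 by 4.26. Of 18 genes that respond to cell dissociation, 2 rose and 15 fell, also adjusted over the list alone (camera adjusted p = 5.39e-06, and 0.591 with an estimated correlation). Lipid storage genes rose in 22 of 30 cases and 1 fell, with 23 and 1 adjusted over the list alone; the droplet coat gene PLIN4 rose by 2.39 and LIPE by 2.77 (camera adjusted p = 8.49e-09, and 0.591 with an estimated correlation). The sterol factor SREBF1 rose by 3.05 and PPARG by 1.40, and of 20 adipogenic regulators 10 rose and 5 fell, also adjusted over the list alone (camera adjusted p = 0.132, and 0.615 with an estimated correlation). Within adipocytes PPARG stood at 155 CPM on day 20 and 206 on day 40, and within precursors at 81.4 and 154. TCA cycle genes rose in 13 of 18 cases and 1 fell, with 14 and 1 adjusted over the list alone (camera adjusted p = 0.00271, and 0.591 with an estimated correlation). Matrix genes showed 3 up and 19 down of 30, also adjusted over the list alone (camera adjusted p = 0.00287, and 0.591 with an estimated correlation). GATA6 (0.20, adjusted p = 0.251) and UCP1 (1.15, adjusted p = 0.345) did not pass. The BMP and TGF-beta list had a median of 0.20, a mean of -0.11 and a test direction up, with 8 members up and 7 down of 23, or 9 and 7 adjusted over the list alone (camera adjusted p = 0.8, and 0.806 with an estimated correlation).

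**Figure D4:**
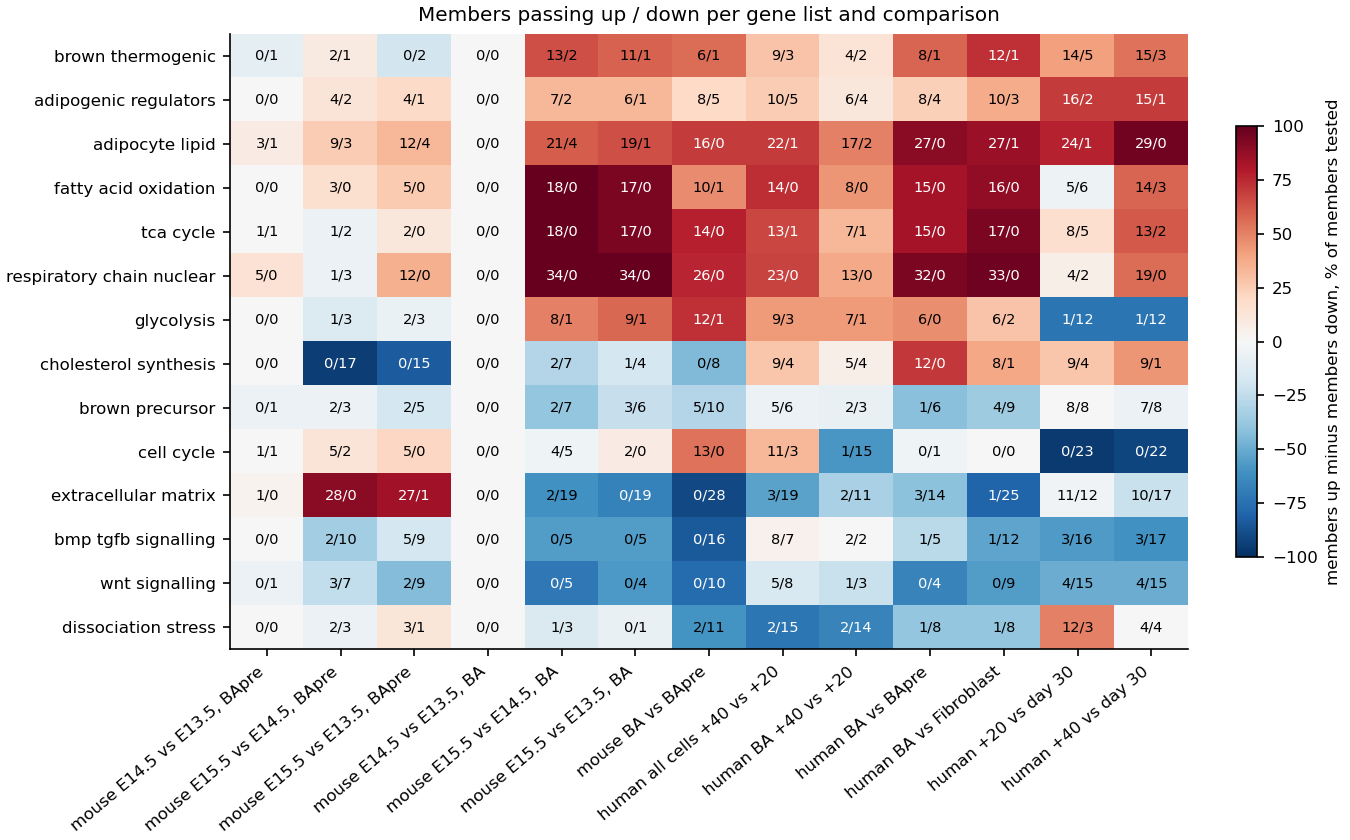
Members passing up / down (numbers in cells) for 14 gene lists (vertical) in 13 comparisons (horizontal), colour giving members up minus members down in % of members tested. All 34 respiratory chain genes rose in mouse adipocytes from E14.5 to E15.5, while 28 of 31 matrix genes rose in precursors.

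Within adipocytes 1459 genes rose and 1559 fell from day 20 to day 40 after replating, of 9945. The total of 3018 was 1076 with DESeq2, and 1177 and 1210 without day 40 replicates 1 and 2. ADIPOQ rose by 2.43 and the lipase LPL by 2.61 on the log2 scale, and SREBF1 by 2.96. Lipid storage genes rose in 17 of 30 cases and 2 fell, with 19 and 2 adjusted over the list alone (camera adjusted p = 3.45e-06, and 0.571 with an estimated correlation). KCNK3, a potassium channel gene of the thermogenic list, rose by 2.90, and 4 of 15 thermogenic genes rose and 2 fell, also adjusted over the list alone (camera adjusted p = 0.278, and 0.571 with an estimated correlation). UCP1 did not pass (-0.33, adjusted p = 0.561), with means of 32.1 ± 29.7 and 28.3 ± 0.639 CPM and only 6 UMIs in replicate 1 of day 20. The UCP1 change was -0.90 (adjusted p = 0.00813) without day 20 replicate 1 and 1.39 (adjusted p = 0.0372) without day 20 replicate 2, with adjusted p up to 0.866 over its alternatives, so its direction stays open. GATA6 did not pass (-0.31, adjusted p = 0.69). Cell cycle genes fell in 15 of 24 cases and 1 rose, also adjusted over the list alone, with the topoisomerase TOP2A falling by 2.36 (camera adjusted p = 2.03e-05, and 0.571 with an estimated correlation). FOSB fell by 7.63 and EGR1, another early response factor, by 3.64; of 18 dissociation response genes 2 rose and 14 fell, also adjusted over the list alone (camera adjusted p = 2.56e-07, and 0.363 with an estimated correlation). Cartilage genes appeared here too: HAPLN1 was at least 91.3-fold higher, with 0 UMIs on day 20. On day 40, 90.4% of the UMIs of 8 cartilage genes lay in 51 of the 1012 adipocytes. Of 3018 called genes, 568 changed beyond their change in fibroblast, SMC and Neuro cells; of 2986 tested there, 1854 (62.1%) moved the same way by at least 50% of the log2 change.

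**Figure D5:**
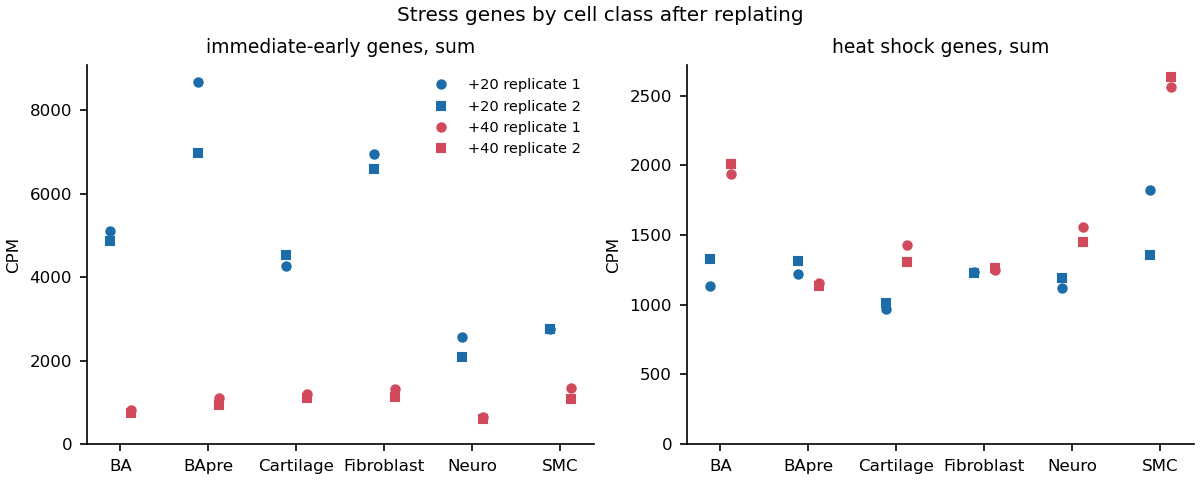
Summed CPM (vertical axes from 0) of 12 immediate-early genes (left) and 6 heat shock genes (right) in each replated class, 1 point per replicate, on day 20 (blue) and day 40 (red) after replating. In adipocytes (BA) the immediate-early sums are 5115 and 4859 on day 20 and 821 and 738 on day 40, while heat shock sums do not fall.

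Adipocytes were set against the other mesenchymal classes of the same 4 replated libraries, again with classes drawn from expression. Against precursors, 1056 genes were higher and 870 lower of 8777. The total of 1926 was 1104 with DESeq2, 584 without the block, and 680 and 638 without day 40 replicates 1 and 2. UCP1 had 207 UMIs in adipocytes and 1 in precursors, a ratio of 129 (22.9 to 5127; adjusted p = 1.28e-05). CIDEA was at least 50.8-fold higher. THRSP, a driver of fat synthesis, was higher by 6.84 and ADIPOQ by 4.93 (949 ± 756 against 31.0 ± 31.7 CPM, SD, n = 4). GATA6 was lower by 2.32 ± 0.29 (SE; 11.2 ± 4.64 against 47.8 ± 15.1 CPM, adjusted p = 0.000207), as were the matrix gene POSTN (by 3.91) and WT1, a mesothelial transcription factor (by 3.47). Lipid storage genes were higher in 27 of 30 cases and lower in 0, with 27 and 1 adjusted over the list alone (camera adjusted p = 7.77e-18, and 0.189 with an estimated correlation). Respiratory chain genes were higher in 32 of 34 cases and lower in 0, with 34 and 0 adjusted over the list alone (camera adjusted p = 1.61e-15, and 0.217 with an estimated correlation). Of 17 cholesterol synthesis genes 12 were higher and 0 lower, with 14 and 0 adjusted over the list alone, among them INSIG1, a brake on sterol synthesis (camera adjusted p = 4.58e-06, and 0.203 with an estimated correlation).

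Against fibroblasts, adipocytes were higher in 1739 genes and lower in 1816 of 11877; the total of 3555 was 1777 without the block, and 2078 and 2248 without day 40 replicates 1 and 2. The UCP1 ratio was 469 (83.2 to 18612), and PPARG was higher by 2.78. DGAT2, the last enzyme of triglyceride synthesis, was higher by 6.49, and the glycerol phosphate enzyme GPD1 by 6.77. Thermogenic genes were higher in 12 of 15 cases and lower in 1, also adjusted over the list alone (camera adjusted p = 1.61e-08, and 0.105 with an estimated correlation). The matrix proteoglycan genes OGN and DCN were lower by 5.56 and 3.85; of 30 matrix genes 1 was higher and 25 lower, with 1 and 27 adjusted over the list alone (camera adjusted p = 1.67e-12, and 0.105 with an estimated correlation). Brown-fat precursor genes were higher in 4 of 14 cases and lower in 9, with 4 and 10 adjusted over the list alone (camera adjusted p = 0.00896, and 0.113 with an estimated correlation). GATA6 was lower by 0.74 ± 0.27 (SE) without passing (adjusted p = 0.0602).

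Replated cultures were compared with day 30 over whole replicates. They sat in separately processed tables and differed in replating as well as in time, so table, replating and time cannot be told apart. Class mix differed too: adipocytes made up 6.87% and 22.3% of cells on days 20 and 40 after replating, while no class of day 30 bore that name. The median mitochondrial share of cells also differed, at 6.88% to 7.62% in the day 30 libraries and 15.6% to 17.5% after replating. The highest share of a deposited cell was 19.8% to 20.0% in the day 30 libraries and 59.6% to 59.9% after replating. The medians and the cells compared thus cover unlike ranges. On day 20 after replating, 5519 genes were higher and 5750 lower of 17502, and on day 40, 4436 and 4632. ADIPOQ was higher by 7.36 on day 20 and 11.31 on day 40, when it stood at 524 ± 34.7 against 0.192 ± 0.105 CPM (SD, n = 2). PPARG was higher by 6.00 and 7.42. UCP1 was higher by 5.02 (adjusted p = 0.0109; 50 against 4 UMIs) and 6.18 (adjusted p = 0.00295; 161 against 4). FOSB was higher by 7.32 on day 20. The tendon factor SCX was lower by 5.94 and 6.38. MYLPF, a light chain of fast muscle myosin, was lower by 6.40 on day 40, and the muscle stem cell factor PAX7 was lower 133-fold (45.3 to 646). GATA6 was lower by 0.63 (adjusted p = 0.0175) on day 20 and by 0.40 (adjusted p = 0.0989) on day 40. On day 20, adipogenic regulators were higher in 16 of 20 cases and lower in 2, also adjusted over the list alone (camera adjusted p = 2.34e-05, and 0.255 with an estimated correlation). Dissociation response genes were higher in 12 of 18 cases and lower in 3, with 12 and 4 adjusted over the list alone (camera adjusted p = 0.00325, and 0.408 with an estimated correlation). On day 40, 29 of 30 lipid storage genes were higher and 0 lower, also adjusted over the list alone (camera adjusted p = 1.76e-16, and 0.131 with an estimated correlation). Of 24 cell cycle genes, 0 were higher and 22 lower, also adjusted over the list alone (camera adjusted p = 4.9e-07, and 0.175 with an estimated correlation). Glycolysis genes were higher in 1 of 15 cases and lower in 12, also adjusted over the list alone, with LDHA, the lactate enzyme, lower by 2.37 (camera adjusted p = 0.000842, and 0.131 with an estimated correlation).

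Human classes were set beside mouse classes by Spearman correlation across the 3000 most variable shared genes, which are not independent replicates. Human skeletal muscle was closest to mouse SkM (rho = 0.449), Cpre to Cpre (0.442), SMC to SMC (0.293) and Schwann-like SC to Schwann cell (0.276). Human precursors of days 6 to 30 were closest to mouse BApre (0.377), with mouse Cpre at the same rounded value. PSM was closest to Macrophage (0.217) and Neuro1 to Epidermis (0.274), in a tissue with neither presomitic nor brain cells as a class. After replating, adipocytes were closest to mouse adipocytes (0.340), precursors to BApre (0.181), cartilage to Cartilage (0.291) and fibroblasts to BApre (0.304). Replated Neuro was closest to Schwann cell (0.247), and the replated class SMC to Macrophage (0.130).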

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

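Tests of the explanations below were chosen only after the results were seen. Of 105 sums over libraries of marker sets and lists, 8 held a library farther from the other 3 than Dixon's ratio allows at the 5% level, where 5.25 would be passed by chance, about 1 in 20. At E15.5 these were the cell cycle list in library 1a at 3889 CPM (others 3659 to 3690), bone markers in 1a at 13.6 (45.0 to 47.6), epidermis markers in 2b at 62.9 (14.6 to 16.9) and cycling markers in 1b at 1828 (1963 to 1987). On day 30 they were pluripotency markers in 2a at 27.3 (63.8 to 64.7), bone markers in 1a at 24.4 (19.7 to 20.3), globin markers in 2a at 3.91 (1.33 to 1.75) and epidermis markers in 2a at 676 (525 to 538). Class differences that differed between groups of samples were marked too. For adipocytes against precursors in mouse, 1468 genes differed between E15.5 and E13.5 (877 up, 591 down). In the replated cultures 513 genes differed between day 40 and day 20 against precursors (247 up, 266 down), and 1106 against fibroblasts (645 up, 461 down). In these 3 cases 8, 8 and 4 gene lists passed, and 0 in each with an estimated correlation (smallest adjusted p 0.204, 0.301 and 0.217).

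The genes that changed in mouse precursors from E13.5 to E14.5 may belong to the libraries more than to the precursors. Of those tested in 4 other classes, 58.5% moved there the same way by at least 50% of the log2 change, which fits a difference shared by the libraries. Embryo sex is unlikely as the whole cause: 51.6% of the calls, 111 genes, were made again without the E14.5 replicate whose Xist was high. Whether the shared part came from stage or from handling stays open.

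Immediate-early genes such as FOSB were lower on day 40 than on day 20 after replating. A changed mix of classes was excluded as the whole cause, since the summed genes fell in all 6 classes between every pair of replicates; the smallest of these falls, in SMC, was -1.04 on the log2 scale. Stress while the cells were dissociated on day 20 could be a cause. The sum of the heat shock genes was not lower on day 40 in adipocytes, with a log2 change of 0.68. Its members differed. HSPA8 rose from 372 to 922 CPM and HSP90AA1 from 227 to 550, and HSPB1 stood at 306 and 310. DNAJB1 fell from 172 to 66.0 CPM, HSPA1B from 41.7 to 23.8 and HSPA1A from 112 to 105. These genes thus neither speak for such stress nor exclude it. Whether such stress or another difference between the days lowered these genes stays open.

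Cartilage genes such as HAPLN1 appeared in adipocytes on day 40 after replating. Free RNA is unlikely, since the top 5% of adipocytes held 90.4% of the UMIs of 8 cartilage genes, against an upper bound of 16.8% if they were spread evenly. Droplets with an adipocyte and a cartilage cell are possible: the 51 cells had a median of 5807 UMIs, above the 5089 of other adipocytes but below the 8718 that the 2 medians add to. Their adipocyte genes stood at 5826 CPM, between 13847 in other adipocytes and 314 in cartilage. Of the 51 cells 23.5% were among the top doublet scores, against 11.8% of other adipocytes, which goes with such droplets. The top 5% of cells also held most of these UMIs in precursors (88.0%), fibroblasts (88.2%) and SMC (78.0%), though cartilage genes made up less of their UMIs (0.0142%, 0.0167% and 0.00805% on average, against 0.0437% in adipocytes). Whether some were cells between these fates stays open.

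Sample labels were also split in other ways to see whether chance could give as many calls. For mouse adipocytes against precursors, 1 of the 100 splits called as many genes as the real 4935, the real split itself, and the next called 2843. Against human precursors it was 1 of the 32 splits (1926, next 1427), and against human fibroblasts 1 of the 32 splits (3555, next 73). The classes had been drawn from the same expression values, so splits that mixed them had to call fewer genes, and these counts leave open what chance could give.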

How the results depend on the processing

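Of 11363 values for 747 pairs of a gene and a comparison that passed, over all alternatives, 10938 kept their side of the threshold, 424 weakened and 1 reversed. Of 1819 values for 117 such pairs that had not passed, 1730 stayed so, 80 came to pass and 9 reversed. The same gene can stand in several pairs. Where a reason is not given, the cause was not tested. Alternatives added after seeing the data were cells with 2000 UMIs or more, cells under 20% mitochondrial UMIs, the highest doublet scores left out, library 2b alone, calls beyond the change in other classes, genes above free RNA, and the block for gene lists. The mouse adipocytes with 1000 or 2000 UMIs and more were not run, since an E13.5 replicate then held fewer than 20 cells. The adipocytes of E13.5 were few, with 48 cells and 72435 and 63095 UMIs in replicates 1 and 2. Marked doublets left out, or the replicate with library 2b alone, moved no count of calls by over 1.5 times.

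With DESeq2, precursors gave 122 calls from E13.5 to E14.5, 1278 from E14.5 to E15.5 and 1364 over both days. Adipocytes gave 55 from E13.5 to E14.5 (7 up, 48 down, against 0 and 3) and, over both days, 919 up and 952 down against 1071 and 689. It gave 5796 calls in the whole replated culture, 1076 in replated adipocytes and 1104 for adipocytes against human precursors. For mouse adipocytes from E13.5 to E14.5, RLE size factors gave 5 calls, no low count filter 55, cells under 20% mitochondrial UMIs 6, the highest doublet scores left out 6, and a and b libraries as separate replicates 0. For precursors over that day, no filter gave 382 and separate libraries 81. Without genes at or below the level of free RNA, 2502 calls stayed in precursors from E14.5 to E15.5, 2436 over both days and 3014 in replated adipocytes. The replated level came from cartilage markers in precursors, fibroblasts, SMC and Neuro. In precursors, fibroblasts and SMC the top 5% of cells held 88.0%, 88.2% and 78.0% of the UMIs of 8 cartilage genes. An even spread would give at most 27.1%, 24.2% and 35.0%, so that level was not free RNA alone.

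Counting only calls beyond the change in other classes left 14, 586 and 724 in precursors (E14.5 against E13.5, E15.5 against E14.5, E15.5 against E13.5), 1 and 2114 in adipocytes for the first and second of these, and 568 in replated adipocytes. With an estimated correlation 0 of 101 list calls stayed; the smallest adjusted p was 0.105.

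The replicate number as a replicate block gave 7 calls in mouse adipocytes from E13.5 to E14.5 and moved no other count by over 1.5 times. Deviations of samples with the same number correlated at -0.017 to 0.067 in mouse, 0.216, 0.176 and 0.116 (3 fits) between replated days, and -0.323 and -0.235 between day 30 and those days. The labels do not pair the samples, and 2 numbers per group are too few to settle it from the data. With no replicate block in the class comparisons, 584 calls were made against human precursors and 1777 against fibroblasts, of which 582 and 1773 were among those made with it. With the block 99 list calls passed, and 8 lists changed sides.

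Leaving out each replicate in turn assumed that a lone sample varied like the others. Counts ranged from 70 to 342 in precursors from E13.5 to E14.5 (E13.5 replicates 1 and 2 left out gave 70 and 78, E14.5 replicates 95 and 142, and E15.5 replicates, which share the fit, 342 and 341). They ranged from 1218 (without E14.5 replicate 1) to 2465 from E14.5 to E15.5, and from 1345 to 2584 over both days (without E13.5 replicates 1 and 2, 1345 and 1453). In adipocytes they ranged from 0 to 100 from E13.5 to E14.5 (0 without either E13.5 replicate or E14.5 replicate 2, 100 without E14.5 replicate 1, 25 and 23 without E15.5 replicates 1 and 2). From E14.5 to E15.5 they ranged from 2122 to 4054 (2288 and 2122 without E15.5 replicates 1 and 2), and over both days from 911 to 2047 (911 and 917 without E13.5 replicates 1 and 2). Mouse adipocytes against precursors gave 3208 to 5208 (3208 and 3264 without E15.5 replicates 1 and 2). The whole replated culture gave 6185 to 10124, and the comparisons with day 30 gave 9301 to 11607 and 6557 to 9336. Without day 40 replicates 1 and 2, replated adipocytes gave 1177 and 1210 (range 1177 to 2939), adipocytes against precursors 680 and 638 (638 to 2597) and against fibroblasts 2078 and 2248 (2078 to 3624).

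Some single genes reversed when a replicate was left out, over these ranges of log2 change; of them only Dkk2 had passed. Without E13.5 replicate 1 they reached 0.62 for Gata3 in precursors (lowest -1.99) and, in adipocytes from E13.5 to E14.5, 8.08 for Zfp467 (-2.90), 0.40 for Hmgcs1 (-0.99) and 0.22 for Tgfbr1 (-0.72), and over both days 6.37 for Dkk2 (-5.94). Without E13.5 replicate 2, Tgfbr2 reached 0.12 (lowest -1.74). In replated adipocytes GATA6 ranged from -1.13 to 0.22 (without day 20 replicate 2), with 0.20 without day 40 replicate 2. UCP1 ranged from -0.90 (without day 20 replicate 1) to 1.39 (without day 20 replicate 2, adjusted p = 0.0372), with adjusted p from 0.00813 to 0.866 over its alternatives. In the whole replated culture GATA6 turned to -0.0596 in cells under 20% mitochondrial UMIs.

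The slope of the precursor share, near 0, turned to -0.048 with 1000 UMIs or more, -0.489 with 2000 or more and -2.67 among mesenchymal cells, where SMC turned to -0.035. Leaving out replicates gave precursor slopes of -0.791 (without E15.5 replicate 1) to 0.735, with -0.005 without E13.5 replicate 2. SkM turned to -0.220 and -0.267 without E13.5 replicates 1 and 2 (highest 1.24), and Mast cell to -0.098 without E15.5 replicate 1 (highest 0.424). The adipocyte slope stayed between 19.5 and 29.7, and 0 to 0 classes passed. That count says little, since leaving out a replicate makes the smallest p that the permutation test can reach larger. edgeR on cell numbers passed 2 classes, with adipocytes at 2.83 log2 per day. On day 10, PSM held 2.99% with 1000 UMIs or more. With 1000 genes 9 of 13 human classes kept their closest mouse class, and 12 with Pearson correlation; of 6 replated classes 5 and 5 did.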

Other observations

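Gata6 was not confined to precursors in the mouse back. The class Dpre held 185 CPM (156 to 218, exact 95% Poisson interval) at E13.5 and 164 CPM (138 to 195) at E14.5, and smooth muscle cells (SMC) held 94.5, 64.8 and 145 CPM at the 3 stages, with replicates 1 and 2 far apart (127 and 65.5, 32.2 and 88.0, and 104 and 210 CPM). Dermis held 3.97 and 5.37 CPM at the first 2 stages. Pparg, the master regulator of fat cells, stood at 170 CPM (108 to 255; 96.6 and 254 CPM in replicates 1 and 2, from 7 and 16 UMIs) in adipocytes at E13.5, before Cidea was seen in them, and at 294 and 302 CPM at the later stages; in precursors it stood at 68.4, 93.8 and 57.8 CPM.

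PPARG was low in the human class BApre of the day 6 to 30 table, whose best marker set was tendon. This class held 0 PPARG UMIs in 129 cells on day 20 (upper limit 8.08 CPM) and 0.978 CPM (0.447 to 1.86) on day 30. The separately named BApre class held 81.4 CPM (61.5 to 106) and 154 CPM (141 to 167) on days 20 and 40 after replating. Adipocytes then held 155 and 206 CPM. CIDEA stood at 32.0 CPM (23.2 to 43.1) and 36.1 CPM (31.3 to 41.5) in replated adipocytes, while precursors held 0 UMIs on both days. DLK1, a preadipocyte marker, went from 2.01 CPM on day 10 to 361.6 on day 20 and 771.6 and 984.2 in the day 30 replicates. EBF2, a factor of brown-fat precursors, was highest on day 20, at 158 CPM, and stood at 57.1 and 53.3 CPM on day 30.

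Libraries with the same number and the suffix a or b were not always closer than other libraries. The spread between them, over that of sampling, was 2.92 for E15.5 libraries 1a and 1b but 23.6 for 2a and 2b, and on day 30 it was 11.4 for 1a and 1b, 40.9 for 2a and 2b and 11.8 for 1a and 2b. Replicates of the other groups lay at 3.30 (E13.5), 6.34 (E14.5), 5.55 and 3.52 (days 20 and 40 after replating). Median mitochondrial shares were 5.99% and 6.12% at E13.5, 6.68% and 6.36% at E14.5 and 9.28% to 15.1% in the E15.5 libraries.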
